A study of Homo sapiens with 6 samples.

How the data were processed

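Total RNA of 6 samples of neural stem cells from the line SA-01 (3 with DMSO, 3 with X5050) was labelled from 100 ng by the Affymetrix whole-transcript protocol and hybridised to 1 array each, per the labels' protocols. The deposited values are log2 signals per probe set (transcript cluster), and the submitters' processing notes name RMA and Partek. Versions, settings and the genome build of the array's annotation are not given in the sources used here, nor is whether RMA was run on these 6 arrays alone. RMA subtracts background, brings the arrays to a common distribution and summarises probes on the log2 scale, which compresses changes of dim probe sets, so folds are on that scale. The array medians (5.68 to 5.75) and quartiles were close but not identical. The values carry no background or detection measure used here, so no probe set was called absent.

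The value table holds 33297 probe sets. The platform annotation pairs 21214 of them with genes: 19460 have 1 gene symbol and were tested, 1754 have several symbols and were named by none, and 12083 are not in that annotation and are unnamed here. The tested probe sets stand for 18417 symbols, 1812 of them sharing a symbol with another probe set, and 558 probe sets of the whole table had values identical to an earlier one, so a count of probe sets can count a gene more than once. Of the tested probe sets 19429 matched a RefSeq gene of the assembly GRCh38.p14 by Entrez identifier, which changed 0 symbols. That table was used only for names and for gene lengths (the span of a gene in that assembly), and no coordinates are given. Subtracting the length trend (loess of the change on log10 length) from the ribosomal protein and proteasome lists was chosen after their values were seen. An SE printed with a list's value after this subtraction, or with a difference between lists, is that of a mean over genes. It treats genes as independent and does not measure the spread between arrays or cultures.

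Groups and replicate numbers come from the sample titles. X5050 was compared with DMSO by limma 3.58.1 (lmFit and eBayes, two-sided, statmod 1.5.0, R 4.3.3) on the deposited log2 values of all 6 arrays, with Benjamini-Hochberg adjustment over 19460 probe sets and a threshold of adjusted p under 0.05. Treatment was the only term. With 3 against 3 arrays a rank-based exact permutation test cannot go below 0.1, and limma goes lower by pooling the spread over genes. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

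The design text gives 6 samples from 3 independent cultures treated with either DMSO or X5050, which was read as each culture receiving both, and the replicate numbers were checked for pairing. The deviations of same-numbered arrays from their group means correlated at 0.365, 0.298 and 0.255 over all probe sets, and those of differently numbered arrays at -0.236 to -0.052. All 3 pairs were above 0.1, so the numbers were taken to pair the samples. The paired fit adds the replicate number as a block, which leaves 2 residual degrees of freedom against 4. It was fixed as an alternative before the data were examined, and its values stand beside results where it changed a call or a count of calls.

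Before the data were examined 38 gene lists were fixed: REST targets and cofactors, neuronal and cell type markers, cell cycle, stress, lipid and other pathways. Of their 669 genes 614 were measured, and genes without a value here were not analysed here. Each list was tested with camera (preset correlation between genes of 0.01) on 1 probe set per gene, the brightest by mean over all arrays, with adjustment over the 38 lists. With the correlation estimated from the arrays 0 of the lists passed in either fit, so no set call holds under that setting. The rotation test fry, which asks whether a list's genes move one way on balance, passed 0 lists with a smallest adjusted p of 0.0652. Its test of change in either direction, which takes no account of a common direction and compares a list with no other genes, had an adjusted p under 0.05 for 6 lists without the block and 16 with it. The 6 were the cholesterol, fatty acid, S phase, neural stem cell and BMP and TGF-beta lists (adjusted p = 0.0236 each) and the interferon list (0.0493).

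The genes named were to be the 12 with the largest rise and the 12 with the largest fall among those past the threshold and with all X5050 values on one side of the DMSO values, skipping unnamed loci, open reading frame names and small or long non-coding RNA symbols. As fewer than 5 passed in a direction, the 5 with the smallest p in each direction were named, and after the data were seen the rule was repeated on the paired fit. REST was always named, with the 10 members of its target list with the smallest adjusted p and 4 members from each other list past the set test, by the paired fit for lists past only there. MVK, SREBF2, ME1, CYP1A1, NES, GJA1 and RIGI were named after their values were seen.

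The fits were tested on simulated data over 19460 probe sets with their real means, 200 of them changed. Each spread was the probe set's own residual variance in the paired fit, before moderation. Culture effects were random draws scaled to the further variance without the block. For the comparison of X5050 with DMSO, the fit without block recovered 19% of genes changed by 0.50 (log2) and 68% of those changed by 1, with 2 false among 89 calls. The paired fit recovered 0% and 44%, with 0 false among 44 calls. In the real data the order was the reverse, with 97 calls in the paired fit and 0 without the block. The simulated shares therefore do not measure what the fits could find here. In a simulation of 38 lists of 20 genes, 1 list was shifted by 0.50 (log2) in all its genes. Under both correlation settings camera found that list and called 0 unchanged lists. Genes were drawn independently there, so it does not test lists of correlated genes. Nor does it test smaller shifts, such as those of most lists called here. Alternatives tried were the moderation of variances, the scaling of arrays, a filter on dim probe sets, array weights, the replicate block, leaving out each array, other adjustment families and thresholds, and other set tests.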

Results

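Gene expression was measured on 6 Affymetrix arrays in neural stem cells (NSCs), self-renewing neural precursors derived here from the human embryonic stem cell line SA-01. Cells at passage 14 were given either the solvent DMSO at 0.1% or the compound X5050 at 100 µM, starting 5 h after plating, and RNA was taken after 24 h. Each treatment had 3 arrays, from 3 independent cultures, read from the design text as each supplying a DMSO and an X5050 sample. The median log2 signal of an array lay between 5.68 and 5.75, and any 2 arrays had a Pearson correlation between 0.984 and 0.993 over 33297 probe sets. The series title calls X5050 an inhibitor of REST, the repressor that binds RE1 elements and holds down neuronal genes outside neurons, so the comparison asks which transcripts differed between X5050 and DMSO. All changes are log2 signal with X5050 minus that with DMSO, and the number of arrays (3 per treatment) limits their precision.

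Among the 5 named genes with the smallest p on the lower side, 4 belonged to lipid metabolism. ACAT2, the cytosolic enzyme that joins acetyl-CoA units, was 1.88-fold lower (log2 change -0.91, SE 0.11, n = 3 per treatment), and FADS2, a fatty acid desaturase, 1.77-fold lower (-0.83, SE 0.10). ERG28, a membrane scaffold of sterol enzymes, was 1.67-fold lower (-0.74, SE 0.093) and FDPS, the farnesyl diphosphate synthase, 1.68-fold lower (-0.75, SE 0.095). LIX1, one of the neural stem cell markers, was 2.60-fold lower (-1.38, SE 0.17). On the other side stood NEGR1, a neuronal adhesion protein (1.72-fold higher, log2 change 0.78, SE 0.11), and RAB27B, a GTPase of vesicle release (1.79-fold, 0.84, SE 0.12). MANBA, a lysosomal mannosidase (1.57-fold, 0.65, SE 0.098), RNF145, a ubiquitin ligase of the endoplasmic reticulum (1.62-fold, 0.70, SE 0.11), and KIAA0825 (1.80-fold, 0.85, SE 0.14) were higher too. None of these 10 genes passed the threshold, with adjusted p = 0.172 for the 5 lower genes and from 0.210 to 0.234 for the higher ones. Without a replicate block 0 of 19460 probe sets rose and 0 fell in the limma fit at an adjusted p under 0.05, while 875 were higher and 949 lower at an unadjusted p under 0.05. The 3 X5050 values lay entirely above or below the 3 DMSO values for 2904 probe sets (14.9%, against 10% by chance).

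When each X5050 sample was compared with the DMSO sample of its own culture, by a replicate block in limma, 37 probe sets rose and 60 fell (37 and 57 gene symbols), and 1374 and 1455 did so at an unadjusted p under 0.05. DHCR7, the reductase of the last step of cholesterol synthesis, fell by 1.65 on the log2 scale (3.14-fold, paired SE 0.099, adjusted p = 0.00236 in the paired fit, n = 3 cultures). LIX1, the arrestin-like ARRDC4 (-1.34) and the transketolase-like TKTL1 (-1.23) also fell. So did the sterol enzymes NSDHL (-1.21), HMGCS1 (-1.18) and MSMO1 (-1.04), the histone H2BC14 (-1.16), the sterol sensor partner INSIG1 (-1.05), the membrane lectin CHODL (-1.01), the mitochondrial co-chaperone DNAJC15 (-0.99) and ACAT2. Among the genes that rose were KIAA1107 (0.99), the lipid-binding myelin protein PMP2 (0.91), the adhesion protein CNTN3 (0.85), the heparan sulfate enzyme NDST3 (0.84), KIAA0825, RAB27B and NEGR1. Others were the coactivator EYA1 (0.76), the channel subunit UNC80 (0.75), the autophagy protein ATG2B (0.73), a probe set annotated to the chromatin protein ANKRD11 (0.72) and the protease ADAMTS3 (0.71). Other probe sets of KIAA0825 (0.82 and 0.26), UNC80 (0.40), ATG2B (0.32) and ANKRD11 (-0.15 to 0.22) did not pass. Those of ANKRD11 lay on both sides of 0, so a rise of that gene is not shown. Of the 10 genes named above from the fit without the block, 5 in each direction, RNF145 alone did not pass in the paired limma fit (adjusted p = 0.0555). At least a doubling or halving was seen for 1 of the probe sets that rose and 14 of those that fell. The mesenchymal marker LUM was also among the genes that fell (-1.09). Without culture 1 the paired fit called 346 probe sets, with 94 of the 97 among them. Without culture 2 it called 81, of which 49 were among the 97, and without culture 3 it called 0. All 97 kept their sign each time. Their selection in the fit to all 3 cultures favours this, so it is no separate support. Without culture 2, UNC80 (adjusted p = 0.0732 in the paired limma fit), ANKRD11 (0.0535), TKTL1 (0.0508) and H2BC14 (0.0648) were among those that did not pass. Without culture 3 the smallest adjusted p in limma was 0.0633, and 1839 probe sets had an unadjusted p under 0.05.

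Genes of cholesterol synthesis and uptake fell together (camera set test adjusted p = 9.02e-29 over 38 lists, and adjusted p = 0.332 with an estimated correlation). All 18 measured members of the list of 24 were lower in X5050 than in DMSO, in each of the 3 cultures, by 1.20-fold for MVK to 3.14-fold for DHCR7. The median log2 change of the list was -0.71, and it was -0.66, -0.92 and -0.56 in cultures 1, 2 and 3. HMGCS1, the synthase acting just before the statin target, was 2.27-fold lower (paired SE 0.10) and NSDHL, which removes sterol methyl groups, 2.31-fold lower (paired SE 0.093), while ACAT2 and FDPS were 1.88-fold and 1.68-fold lower. SREBF2, which encodes the transcription factor that drives this pathway, fell by 0.58 (1.49-fold, paired SE 0.093, adjusted p = 0.0488 in the paired fit). Without the replicate block 0 members passed over all genes and 18 fell when adjusted over the list alone, and in the paired fit 12 fell over all genes and 18 when adjusted over the list alone. The 3 X5050 values were separate from the 3 DMSO values for 100% of the 18 genes, against 10% by chance in either direction and 14.9% of all tested probe sets.

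**Figure D1:**
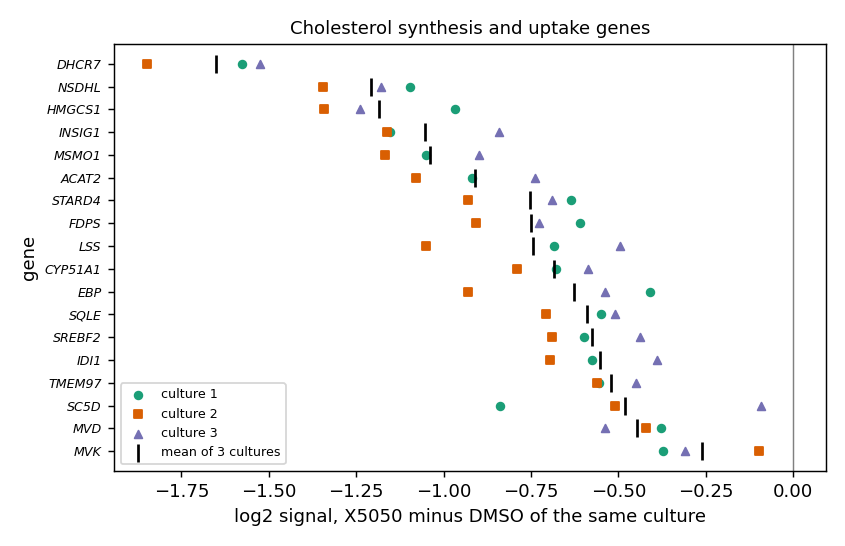
Log2 signal with X5050 minus that with DMSO of the same culture (horizontal axis) for the 18 measured cholesterol synthesis and uptake genes (vertical axis), with a symbol for each of the 3 cultures and a bar for their mean. Every point lies below 0, with DHCR7 at -1.65 and MVK at -0.26 as the lowest and highest means.

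The fatty acid synthesis list, which shares part of its regulation with cholesterol synthesis, fell with a median of -0.19 over 12 genes, 9 of them below 0 (camera adjusted p = 0.00234, and adjusted p = 0.982 with an estimated correlation). FADS2 had the smallest p of its members, followed by the citrate lyase ACLY (-0.47, SE 0.12), the stearoyl-CoA desaturase SCD (-0.49, SE 0.13) and the desaturase FADS1 (-0.20, SE 0.079). Over all genes 0 members passed without a replicate block and 2 fell in the paired fit, FADS2 and the malic enzyme ME1 (-0.94). Adjusted over the list alone 3 fell without the block, while 5 fell and 1 rose with it. The adjusted p of the list was 0.0967 without DMSO replicate 1.

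REST mRNA itself was 8.37 ± 0.12 with DMSO and 8.31 ± 0.088 with X5050 (SD, n = 3 each), a log2 change of -0.057 (95% interval -0.28 to 0.17, adjusted p = 0.917). Genes known as REST targets through RE1 elements rose by a small amount as a group (camera adjusted p = 0.00185, and adjusted p = 0.982 with an estimated correlation). Of the 48 measured members of 50, 38 were above 0 and 10 below, with a median log2 change of 0.12 and a mean of 0.14. The synaptic fusion protein SNAP25 was 1.58-fold higher (log2 change 0.66, paired SE 0.087) and rose in the paired fit (adjusted p = 0.0328). The next 9 members by p-value were the muscarinic receptor CHRM4 (0.28), the granins SCG2 (0.65) and CHGB (0.35), the glycine receptor GLRA3 (0.17, at a signal of 3.35 with DMSO, below the lower quartile of every array), PTPRN of secretory granules (0.20), the sodium channel SCN3A (0.43), the adhesion molecule L1CAM (0.14), SEZ6 (0.30) and the vesicle-priming protein UNC13A (0.22), with adjusted p from 0.411 to 0.690 without a replicate block. Of the 48 genes 16 were higher in all 3 cultures and 2 were lower in all 3. The 3 X5050 values were separate from the 3 DMSO values for 12.5% of the 48 genes, no more than the 14.9% of all tested probe sets. Over all genes 0 members passed without the block and 1 rose with it, and adjusted over the list alone the counts were 0 and 2. Without DMSO replicate 3 and without the block SCG2 stood at 0.39. With 1 array left out and no block CHGB ranged from 0.15 to 0.52 and SCN3A from 0.21 to 0.55. SEZ6 ranged from 0.14 to 0.49 and UNC13A from 0.14 to 0.35.

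The median change of the 48 REST target genes was 0.12, 0.17 and 0.019 in cultures 1, 2 and 3, beside lower mesenchymal and matrix genes, whose median was -0.33, -0.16 and -0.065 in these cultures. The REST target median was 0.070 without DMSO replicate 1 (adjusted p = 0.0308) and 0.073 without culture 2 in the paired fit (adjusted p = 0.0190). The 15 measured genes of the REST complex and REST turnover had a median of 0.039 (adjusted p = 0.951), the 19 pan-neuronal markers -0.078 (adjusted p = 0.904), the 21 proneural and neurogenic factors 0.045 (adjusted p = 0.712) and the 19 voltage-gated ion channels 0.078 (adjusted p = 0.342).

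**Figure D2:**
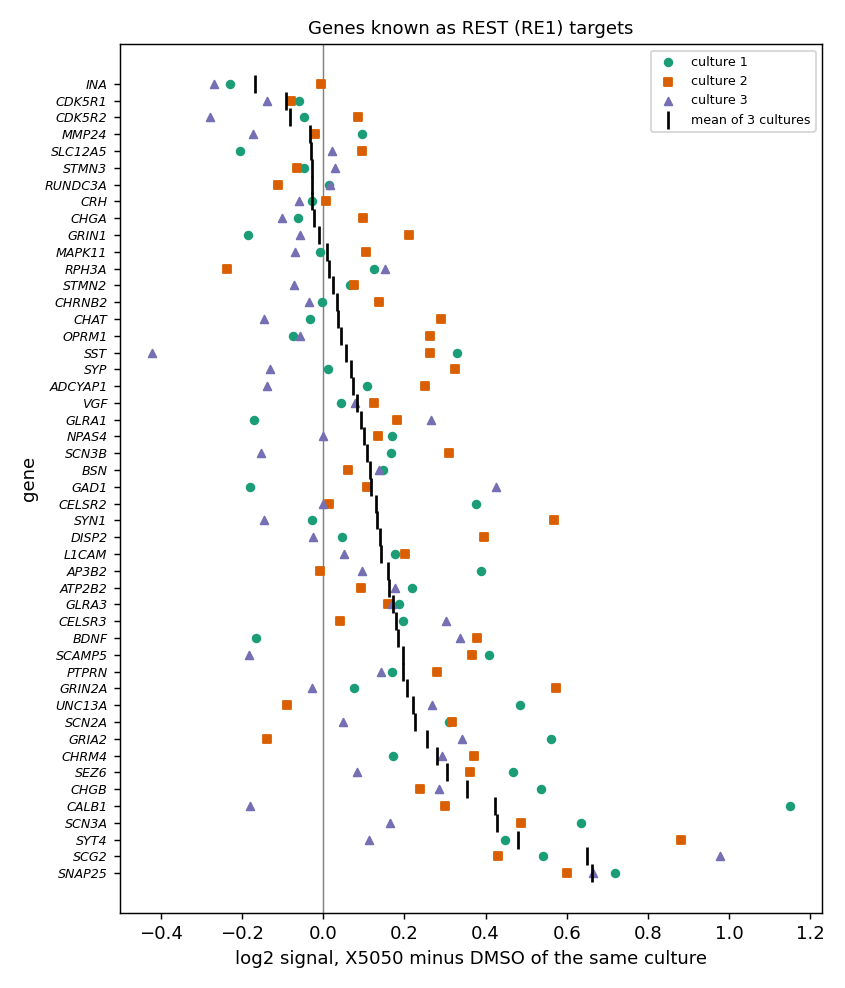
Log2 signal with X5050 minus that with DMSO of the same culture (horizontal axis) for the 48 measured REST target genes (vertical axis), with a symbol for each of the 3 cultures and a bar for their mean. Means lie above 0 for 38 genes, and SNAP25 has the highest mean, 0.66.

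Synaptic vesicle genes rose as a list only with the replicate block (21 genes, median 0.088, paired camera adjusted p = 0.0401 and adjusted p = 0.743 with an estimated correlation, against 0.146 without the block). The members with the smallest p in the paired fit were SNAP25, the calcium sensor SYT1 (0.48, paired SE 0.093), the synapsin SYN3 (0.50, paired SE 0.11) and the calcium sensor SYT4 (0.48, paired SE 0.14). SNAP25 and SYT4 are also in the REST target list. SYT4 stood at 0.28 without culture 2 in the paired fit, and without the block it ranged from 0.24 without DMSO replicate 2 to 0.90 without DMSO replicate 3, while SYN3 stood at 0.27 without X5050 replicate 2. In the paired fit 1 member rose over all genes and 4 when adjusted over the list alone, and without the block these counts were 0 and 0. The adjusted p was 0.0819 without culture 1, 0.241 without culture 2 (median 0.011) and 0.00224 without culture 3 (median 0.15).

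Mesenchymal and matrix genes, markers of a cell type other than neural stem cells, fell in the paired fit (14 of 17 genes below 0, median -0.18, paired camera adjusted p = 9.09e-05 and adjusted p = 0.743 with an estimated correlation, against 0.141 without the block). The collagen-binding LUM was 2.12-fold lower (log2 change -1.09, paired SE 0.15), and the smooth muscle protein TAGLN (-0.89, paired SE 0.22), the matrix protein POSTN (-0.87, paired SE 0.23) and the homeobox factor PRRX1 (-0.35, paired SE 0.087) were lower in all 3 cultures. Cultures differed widely in these genes, with an SD over the 3 DMSO arrays of 1.76 for TAGLN, 1.57 for POSTN and 0.83 for LUM. Without DMSO replicate 1 and without the block, TAGLN stood at -0.040, POSTN at 0.024, PRRX1 at 0.15 and LUM at -0.61, and LUM at -0.55 without X5050 replicate 2. Without the block TAGLN and POSTN reached -1.80 and -1.42 without DMSO replicate 3, and -1.73 and -1.43 without X5050 replicate 1, while TAGLN was -0.33 without X5050 replicate 3 and POSTN -0.47 without X5050 replicate 2. In the paired fit TAGLN was -0.54 without culture 2 and POSTN -0.53 without culture 1. Over all genes 1 member fell in the paired fit and 0 without the block, and adjusted over the list alone 6 fell and 1 rose in the paired fit and 0 passed without it. The median was -0.33, -0.16 and -0.065 in cultures 1, 2 and 3.

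Aryl hydrocarbon receptor targets also fell only in the paired fit (7 genes, 5 below 0, median -0.065, paired camera adjusted p = 0.0326 and adjusted p = 0.743 with an estimated correlation, against 0.593 without the block), beside the lower mesenchymal genes. The cytochrome CYP1B1 fell by 1.03 (2.05-fold, paired SE 0.086, adjusted p = 0.00815 in the paired fit). The quinone reductase NQO1 stood at -0.74 (paired SE 0.12), the receptor AHR at -0.23 (paired SE 0.12) and TIPARP at 0.13 (paired SE 0.087). Without DMSO replicate 1 and without the block AHR stood at 0.36, NQO1 at -0.21 and CYP1B1 at -0.57, and NQO1 was -1.21 without DMSO replicate 3, -1.24 without X5050 replicate 1 and -0.42 without X5050 replicate 3. CYP1B1 was the 1 member past over all genes with the block (0 without it), and 2 fell when adjusted over the list alone (0 without it). TIPARP ranged from 0.046 to 0.23 with 1 array left out and no block. The classical target CYP1A1 had a log2 change of -0.035 (SE 0.15). Without culture 1 the adjusted p of the list was 0.0554, and its median was -0.16 without culture 3.

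Genes of the G2 phase and mitosis fell as a list, with 19 of 26 below 0 and a median of -0.17 (camera adjusted p = 8.49e-05, and adjusted p = 0.982 with an estimated correlation). The mitotic kinase PLK1 was 1.55-fold lower (log2 change -0.63, SE 0.13) and had the smallest p of the list, followed in order of p by BIRC5 (-0.43, SE 0.11), CDC20 (-0.36, SE 0.098) and KIF20A (-0.41, SE 0.12). S phase genes fell by less (15 of 25 below 0, median -0.073, camera adjusted p = 0.0345, and adjusted p = 0.982 with an estimated correlation). The members with the smallest p were the replication factors CDC45 (-0.36, SE 0.085), GINS1 (-0.40, SE 0.10), MCM4 (-0.28, SE 0.081) and MCM5 (-0.29, SE 0.094). In neither list did a member pass over all genes in either fit. Adjusted over the list alone 1 G2 and mitosis gene fell without the replicate block and 5 with it, and 0 S phase genes did in either fit. The S phase call was lost with the block (adjusted p = 0.0768), after another quantile normalization (0.222) and without dim probe sets (0.120). It was also lost with the median of a gene's probe sets (0.0529) and without X5050 replicate 2 (0.0774, median -0.0086). Without DMSO replicate 2 both calls were lost, with adjusted p = 0.472 and a median of -0.032 for S phase and adjusted p = 0.325 and a median of -0.042 for G2 and mitosis. The medians were -0.044 without DMSO replicate 3 for S phase and -0.11 without X5050 replicate 1 for G2 and mitosis. Without culture 2 in the paired fit they were 0.020 for S phase and -0.094 for G2 and mitosis.

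Ribosomal protein genes fell by a small amount. All 21 measured members were below 0 as deposited, with a median of -0.12 (camera adjusted p = 8.49e-05, and adjusted p = 0.982 with an estimated correlation). The median was -0.14 with arrays centred on their medians and -0.064 after another quantile normalization. RPL35 was 1.48-fold lower (log2 change -0.56, SE 0.11), followed in order of p by RPL8 (-0.35, SE 0.14), RPS16 (-0.27, SE 0.11) and RPS14 (-0.33, SE 0.14). With 1 array left out and no block RPL8 ranged from -0.45 to -0.22, RPS16 from -0.35 to -0.17 and RPS14 from -0.46 to -0.18. After the trend of the change with gene length (GRCh38.p14) was subtracted the ribosomal protein median was -0.097 and the proteasome median -0.13. The SEs of the means over genes were 0.033 and 0.021. Random gene lists matched on mean signal were not drawn for either list, so brightness as a source was not tested. Proteasome genes fell too, with 22 of 23 below 0 and a median of -0.15 (camera adjusted p = 2.37e-05, and adjusted p = 0.982 with an estimated correlation), among them PSMB6 (-0.35, SE 0.099), PSMD12 (-0.35, SE 0.12), PSMB2 (-0.24, SE 0.083) and PSMC1 (-0.24, SE 0.095). PSMD12 ranged from -0.46 to -0.23 with 1 array left out and no block. Over all genes 0 members of both lists passed in either fit, and adjusted over the list alone 1 ribosomal protein gene and 0 proteasome genes fell in either fit. The ribosomal protein median was -0.0057, -0.21 and -0.27 in cultures 1, 2 and 3. Without DMSO replicate 3 its adjusted p was 0.0711 with a median of -0.052, and its median was -0.21 without DMSO replicate 1, -0.22 without DMSO replicate 2 and -0.24 without culture 1 in the paired fit.

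Markers of cell identity outside the lists above showed no shift past the set test. The neural stem cell list had a median of -0.013 over 19 genes (adjusted p = 0.364), and adjusted over the list alone 2 of its members fell, LIX1 and the intermediate filament gene NES (-0.42, SE 0.10). Medians were 0.037 for astrocyte markers (adjusted p = 0.872), 0.026 for oligodendrocyte lineage markers (0.927), 0.023 for pluripotent cell markers (0.745), 0.043 for neural crest markers (0.209), -0.0080 for endothelial and blood cell markers (0.961) and 0.048 for epithelial markers (0.951). In the paired fit the gap junction gene GJA1 of the astrocyte list fell by 0.61 (paired SE 0.094, adjusted p = 0.0444).

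Stress and signalling lists did not pass either. The integrated stress response genes had a median of 0.061 (adjusted p = 0.312), chaperones of the endoplasmic reticulum -0.081 (0.312) and NRF2 targets -0.060 (0.927). The median was -0.018 (0.961) for heat shock genes, 0.028 (0.961) for p53 targets, -0.044 (0.370) for apoptosis genes and 0.023 (0.951) for hypoxia and glycolysis genes. It was -0.017 (0.904) for metallothionein and zinc response genes and 0.046 (0.480) for iron handling genes. The inflammatory list stood at 0.014 (adjusted p = 0.927), the interferon list at 0.0012 (0.904), with RIGI higher in the paired fit (0.55, adjusted p = 0.0488), and immediate early genes at 0.068 (0.342). Medians were -0.018 (0.904) for Notch genes, -0.016 (0.951) for Wnt targets, -0.044 (0.927) for sonic hedgehog genes, -0.054 (0.961) for BMP and TGF-beta targets and -0.072 (0.141) for oxidative phosphorylation genes. Over the 31 lists that did not pass without the replicate block, 0 members passed over all genes, and adjusted over the list alone 5 rose and 2 fell. With the block these counts were 2 rising and 5 falling over all genes and 21 each way when adjusted over the list alone. The median, mean and test of the REST complex, p53, heat shock and hypoxia lists differed in sign.

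**Figure D3:**
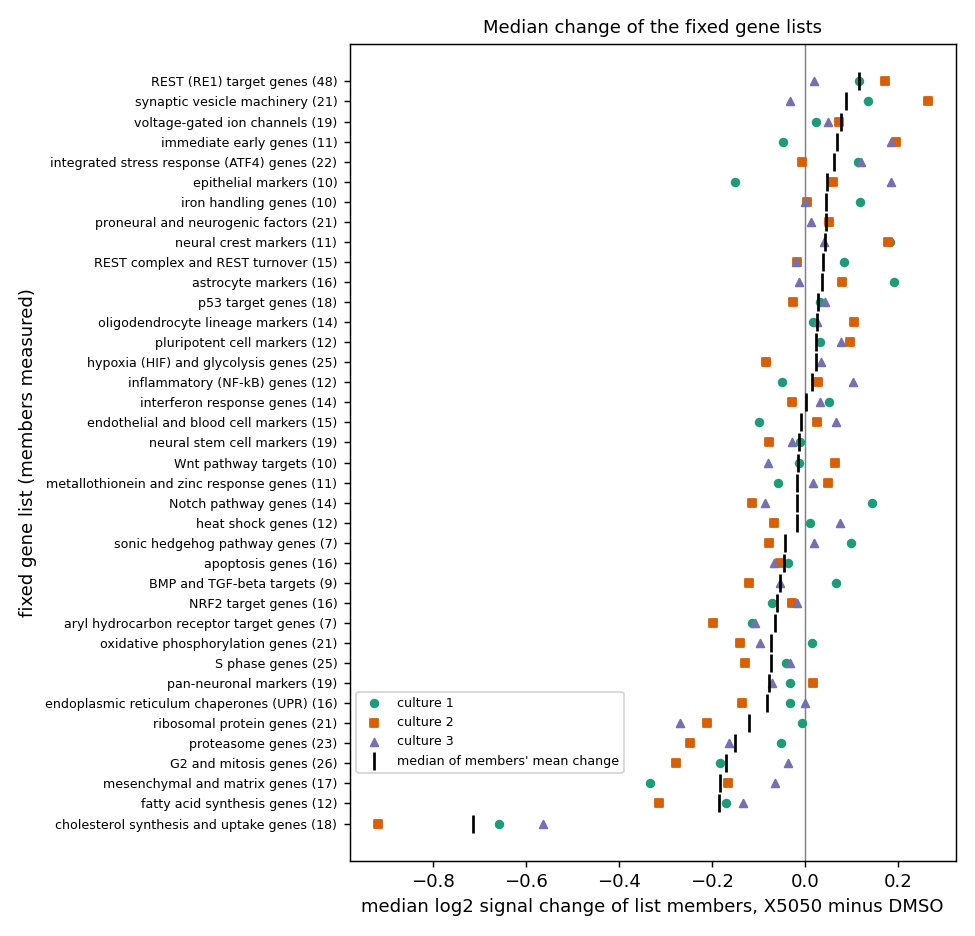
Median log2 signal change of the measured members (horizontal axis, X5050 minus DMSO) for each of the 38 gene lists (vertical axis, members measured in brackets), with a symbol for each of the 3 cultures and a bar for the median of the members' mean changes. The cholesterol list stands apart at -0.71, and the other lists lie between -0.19 and 0.12.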

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

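The combinations of the replicate block with another choice, and the random block, were chosen after the data were seen. Without a block limma gave 0 genes that rose and 0 genes that fell under every setting run for these counts, except that H2BC14 fell without DMSO replicate 1 (0 to 1 over the 6 arrays left out), and with the replicate number as a random block the counts were also 0 and 0. The replicate block gave 37 genes that rose and 60 genes that fell, 31 of the 69 genes named besides REST among them. With the block the counts were 31 and 68 after centring arrays on their medians (89 of the 97 paired calls shared), 18 and 33 after another quantile normalization (51 shared), 118 and 147 with an intensity trend and robust moderation (97 shared), 90 and 92 without dim probe sets, which are fewer tests, and 68 and 74 with array weights (97 shared). Leaving out a culture gave 0 to 113 that rose and 0 to 233 that fell, 41 and 40 without culture 2 (49 of the 97 paired calls shared) and 0 of each without culture 3, with 4 arrays left in the fit. REST mRNA kept its sign and never passed, between -0.12 and -0.00035 with an array left out and -0.12 and -0.0067 with a culture left out. The REST target list kept its call except with an estimated correlation (adjusted p = 0.982, and 0.743 with the block) and with fry (0.391, and 0.356 with the block), and ranged from 2.26e-05 to 0.0374 with an array left out and 1.37e-06 to 0.0190 with a culture left out. The cholesterol list was lost under the same settings (0.332 and 0.743 estimated, 0.0652 and 0.212 by fry) and otherwise lay between 4.52e-28 and 8.00e-23 with an array left out, and 1.45e-30 and 1.27e-28 with a culture left out. Of the lists other than REST targets 6 passed without the block, 0 with an estimated correlation or fry's directional test in either fit, and 5 to 10 with an array left out (10 without X5050 replicate 1) or 7 to 10 with a culture left out (10 without culture 3). Of 1441 alternative values of the 69 genes 5 changed sign: PRRX1 ranged from -0.84 to 0.15 (0.15 without DMSO replicate 1, 0.0021 without X5050 replicate 2), POSTN from -1.43 to 0.024 (without DMSO replicate 1), and AHR from -0.68 to 0.36 (0.36 without DMSO replicate 1, 0.073 without X5050 replicate 2). The cause was not tested, though a lone array left out of a treatment also leaves its culture unbalanced. Beyond the calls named with the results, the block changed none. Dim genes are limited by background, and GLRA3, at 3.35 with DMSO, lay below the lower quartile of every array (4.05 to 4.21).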

Other observations

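The histone, protocadherin, small RNA, YAP and LXR gene groups, single genes outside the naming rule, the comparison of REST targets with other neuronal genes, the length correction of these groups, the comparison of length trends between arrays of the same treatment, and how the LXR target test was read were chosen after some results had been seen. The p-values of these 5 groups are therefore descriptive and are no independent test. Replication-dependent histone genes, whose transcripts lack a poly(A) tail and peak in S phase, were lower in X5050: 55 of 57 lay below 0, with a median log2 change of -0.40 (camera adjusted p = 2.19e-21 over 5 groups, and adjusted p = 0.209 with an estimated correlation). Their median was -0.096, -0.49 and -0.54 in cultures 1, 2 and 3, and H2BC14 fell in the paired fit (-1.16). Histone genes are short (median length 0.487 kb in GRCh38.p14). After the trend of the change with gene length was subtracted their median was -0.37 (SE of the mean over genes 0.032, not over cultures). Beta protocadherins, clustered adhesion genes, were below 0 for 16 of 18 genes (median -0.34, adjusted p = 5.37e-09, and adjusted p = 0.163 with an estimated correlation), with PCDHB14 (-0.86) and PCDHB13 (-0.62) past the threshold in the paired fit. Small nucleolar and Cajal body RNAs were below 0 for 122 of 192 (median -0.079, camera adjusted p = 6.77e-05, and adjusted p = 0.209 with an estimated correlation), with 4 that fell in the paired fit. Their median was -0.032 after the length trend was subtracted (SE of the mean over genes 0.017). YAP and TEAD targets had 12 of 16 below 0 (median -0.13, adjusted p = 0.0205, and adjusted p = 0.481 with an estimated correlation), but their median was -0.29, -0.25 and 0.11 in cultures 1, 2 and 3. The mesenchymal and matrix genes, which fell in the paired fit (adjusted p = 0.743 with an estimated correlation), had medians of -0.33, -0.16 and -0.065 in these cultures.

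Further genes that fell in the paired fit were TXNIP (log2 change -0.74, paired SE 0.11, adjusted p = 0.0429), a thioredoxin-binding relative of ARRDC4 (-1.34), MMAB (-0.90, adjusted p = 0.0177), a cobalamin enzyme encoded beside MVK, PNPLA3 (-0.65, adjusted p = 0.0423), a lipid droplet protein, and the YAP target CCN2 (-1.13, adjusted p = 0.0350), beside the lower mesenchymal genes (median -0.18). LHFPL3 had the largest rise of any paired call (1.10, adjusted p = 0.0488), with overlapping groups. Each of these genes moved the same way in all 3 cultures.

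The drop of the cholesterol genes (adjusted p = 0.332 with an estimated correlation) was set against technical explanations. Of 10000 random lists matched on mean signal none had a median as low (share 1e-04, the smallest they can give, with random medians from -0.19 to 0.18). Subtracting the trend with gene length left the list at -0.70 (SE of the mean over genes 0.080, -0.71 before), and 3 of 3 cultures had a median below -0.2. These values argue against brightness, length and a single culture. Of the 10 splits of the arrays 1, the real one, gave a median as far from 0 (0.71, highest other 0.40, and from -0.29 to 0.29 among the other 3 that part every culture), and 10 splits are too few for a share under 0.05. A surplus of sterols, which would switch this pathway off and LXR targets on, may be the cause and stays open: the 10 LXR targets had a median of 0.054 (camera adjusted p = 0.306), and although the interval of their mean (-0.050 to 0.18) excluded the 0.2 set as a bound beforehand, members lay on both sides (ABCA1 0.31, NR1H3 -0.13), so that bound decides nothing. A direct effect of X5050 on the pathway is a hypothesis that these arrays do not test.

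The rise of REST targets was small (paired camera adjusted p = 0.000140, and adjusted p = 0.743 with an estimated correlation), with release from repression as a candidate explanation that was not tested itself, and the tables argue against brightness and length as the source. No random list matched on mean signal had a median as high (share 1e-04, the smallest possible, random medians from -0.087 to 0.094). The mean was 0.13 (SE over genes 0.025) after the length trend was subtracted and 0.14 before. Another mix of cells stays open, with the mesenchymal and matrix genes lower (median -0.18) and, like the REST targets, least changed in culture 3 (-0.065 and 0.019), and so do more neurons, which would raise other neuronal genes alike: outside the REST list the mean of 17 pan-neuronal markers differed from that of the REST targets by -0.15 (SE 0.051) and that of 17 ion channels by -0.11 (SE 0.043), but that of 17 synaptic vesicle genes by -0.053 (SE 0.060). Of the 10 splits 2 gave a median as far from 0 (real 0.12, highest other 0.12), so the splits do not set the real grouping apart for this list. In any case 10 splits are too few for a share under 0.05. The other of the 2 sets both arrays of culture 1 and DMSO replicate 2 against both of culture 3 and X5050 replicate 2. It mixes a difference between cultures with the treatment difference of culture 2. The other splits that part every culture reached 0.082.

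The longest genes tended to be higher in X5050: in 5 equal groups by gene length, from the shortest to the longest, the median changes were -0.0046, -0.011, -0.0010, 0.015 and 0.052. Across 18386 genes, which are not independent, the change had a Spearman correlation of 0.17 with gene length (GRCh38.p14), and genes that rose in the paired fit had a median length of 157 kb, those that fell 16.5 kb and all genes 24.5 kb. Brightness (partial correlation 0.19 given mean signal) and neuronal genes (0.17 without 120 genes of the neuronal lists) are argued against as the whole source. The correlation passed 0.1 in 2 of 3 cultures (0.15, 0.013 and 0.23), which goes against 1 culture as the whole source but decides little, since arrays of the same treatment differed by as much. Of the 6 differences between arrays of the same treatment, which also span cultures, 2 had a correlation as large as the middle one of these (0.16 and 0.24). Both involve DMSO replicate 3, which also enters the largest treatment correlation (0.23, culture 3), and the others reached at most 0.11. Array quality or RNA integrity varying between samples may be the source but stays open, and a biological one was not tested.

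Other splits of the samples bear on the counts. Without the block 10 of 10 splits gave as many genes in limma, an outcome that a real count of 0 fixes and that tests nothing (real 0, highest other 0, with 1824 in the real split and at most 1473 in the others at an unadjusted p under 0.05). Of the 4 that swap treatments within cultures 1, the real one, gave as many with the block (real 97, highest other 0, with 2829 and at most 709 unadjusted). Both sets of splits are too few for a share under 0.05. For lists past the camera test 7 of 10 splits gave as many (real 7, highest other 17). The number of lists past that test therefore does not set the real grouping apart from the others. The split with 17 lists is the one named above that sets culture 1 against culture 3, and points to a structure of the samples, and the other 3 splits that part every culture gave 7, 5 and 0 lists.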
